A study of Mus musculus with 12 samples.

How the data were processed

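The series holds poly-A selected RNA from mouse hippocampus, prepared with TruSeq kits and sequenced as paired 100 bp reads on an Illumina HiSeq, per the labels. N40K is a truncated U1-70K expressed in neurons from a modified CaMKIIa promoter, on the C57BL/6J strain. The authors deposited FPKM values, fragments per kilobase of transcript and per M mapped reads, in 1 table for the whole series with a column per library. The submitters' processing notes name CASAVA, STAR, BWA and the mm9 genome build without their roles or versions. The counting tool, the gene annotation and the strand setting were not given in the sources used here, so genes that overlap another gene were marked as uncertain. All 12 columns matched library names in the labels, and 0 columns were left unmapped.

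The table held 23352 gene entries, 128 of them with joined names of genes that the authors did not separate. Of all entries 23025 (98.6%) matched GENCODE M21. That annotation lies on another genome build, so it was used only for names, transcript lengths, GC content, overlaps and neighbours, and no coordinates are given. The highest share of identical values between any 2 libraries was 0.016% of the genes at 1 FPKM or more in every library, so no library was a copy of another. Each library was counted as a separate mouse, which these values cannot test. FPKM sums ran from 309358 to 350760 per library. Depth was recovered from the steps between low FPKM values of 1143 receptor genes with 1 coding length. The estimates were 84.1, 84.1 and 78.0 M (mega) reads for wild type at 3 months, 97.1, 90.5 and 39.96 for transgenic at 3 months, 64.4, 44.4 and 97.1 for wild type at 12 months, and 42.8, 90.2 and 65.3 for transgenic at 12 months. Between 52.2% and 69.0% of these values came out whole within 0.02 of a read, so the depths are approximate and no count test was run.

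Values were tested as log2(FPKM + 1), without further scaling, for genes with at least 1 FPKM in at least 3 of the 12 libraries. Fold changes are on that scale, which understates the change of genes with low values. One limma model (limma 3.58.1 in R 4.3.3) with a mean for each of the 4 groups gave 5 contrasts: genotype at 3 months, at 12 months and averaged over both, their difference (the interaction), and age. Tests were two-sided with eBayes and a mean-variance trend, Benjamini-Hochberg adjustment over the genes of a contrast, and a threshold of 0.05. Adjusted p-values of genes in the text come from limma. Gene lists, 29 for biology and 1 of sex-chromosome genes, were tested with camera of limma at a preset correlation of 0.01, adjusted over the 30 lists of a contrast, and again with an estimated correlation, under which 0 lists were called in any contrast. Members were counted as called over all genes tested and again adjusted over the list alone. The signs of median, mean and test differed in some lists that were not called, such as GABA receptors averaged over both ages (median 0.015, mean -0.065). Levels of a list per library are means over its members after subtracting each gene's mean over the 12 libraries.

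Groups, tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The rule took Snrnp70, the 12 largest rises and 12 largest falls per genotype contrast among called genes without overlap between the groups of an age, the 5 largest each way for the interaction and for age, and for each list up to 4 members with the smallest p and any member called. Alternatives were pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, median-ratio scaling, quantile normalization, Xist as a covariate, robust eBayes, the replicate number as a block, each age fitted alone and each library left out in turn. Ttr as a covariate and the removal of each library's lowess trend (span 0.3) against transcript length or GC content were added after seeing the data. Other splits of the libraries, 10 for 3 against 3 and 100 drawn with a fixed seed otherwise, were tested in the same way. After seeing the data the interaction splits were repeated with the averaged genotype effect removed from the values. Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 prepared the tables and drew the plots.

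The procedure was tested on simulated data with 200 changed genes among 13945. At 3 months it recovered 58.2% of genes changed by 0.5 on the log2 scale and 98.5% of those changed by 1, with 12 false calls (6.56% of calls). At 12 months it recovered 68.7% and 100%, with 9 false calls (4.79%), and averaged over both ages 97.0% and 100%, with 17 false calls (7.91%). Each unchanged gene had the same simulated mean in every library, with independent noise of the same dispersion at both ages. Differences between libraries in sex, dissection, transcript length trend or GC trend were not simulated. These shares thus do not measure the recovery or false calls of the real comparisons, nor a difference between the ages. The labels gave no sex, and 3 mice per group set the precision of each comparison. Exon usage and splicing were not analysed here, since gene-level values hold no exon or junction counts.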

Results

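Messenger RNA was profiled in the hippocampus of mice that express N40K, a truncated form of the splicing protein U1-70K linked to Alzheimer's disease, in their neurons, and in wild-type mice. U1-70K is encoded by Snrnp70 and belongs to the U1 small nuclear ribonucleoprotein particle (U1 snRNP), which recognises the splice site at the start of an intron. The 12 libraries formed 4 groups of 3 mice, wild type and N40K transgenic at 3 and at 12 months of age. The deposited FPKM values covered 23352 gene entries, of which 13945 passed the expression filter. Depth recovered from the steps between low values ran from 39.96 to 97.08 M (mega) reads per library. Correlations of log2 values within groups ran from 0.988 to 0.997. The first principal component held 48.3% of the variance and separated the ages, and the second held 17.8% and separated the genotypes. The labels gave no sex. Xist was at 14.6 and 13.5 FPKM in replicates 2 and 3 of the 3-month wild-type group and at 17.3 FPKM in replicate 3 of the 3-month transgenic group, with Y-linked Ddx3y near 0 in the same libraries. Xist was at 0.112 FPKM or less in the other 9, with Ddx3y at 13.9 FPKM or more. These reads mark the former libraries as female and the latter as male. Sex was thus unbalanced between the ages and between the 3-month genotypes.

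Snrnp70 reads separated the genotypes in every library. At 3 months Snrnp70 measured 173 ± 10.5 FPKM in wild-type and 392.4 ± 13.1 FPKM in transgenic mice (mean ± SD, n = 3), a ratio of 2.27. At 12 months it measured 122 ± 23.01 and 294.5 ± 31.95 FPKM (SD, n = 3), a ratio of 2.41. The log2 difference was 1.18 ± 0.12 (SE) at 3 months, with a limma adjusted p of 1.7e-04, and 1.27 ± 0.12 at 12 months, with an adjusted p of 9.33e-05. The transgene sequence was not given in the sources used here, so reads of the transgene and of the endogenous gene could not be separated. Hnrnpu, which encodes an abundant nuclear RNA-binding protein, rose by a similar factor, from 120 ± 2.03 to 257.8 ± 2.17 FPKM at 3 months and from 113 ± 6.92 to 277 ± 15.7 FPKM at 12 months (SD, n = 3). Its log2 difference averaged over both ages was 1.19 ± 0.04, with an adjusted p of 2.4e-08.

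**Figure D1:**
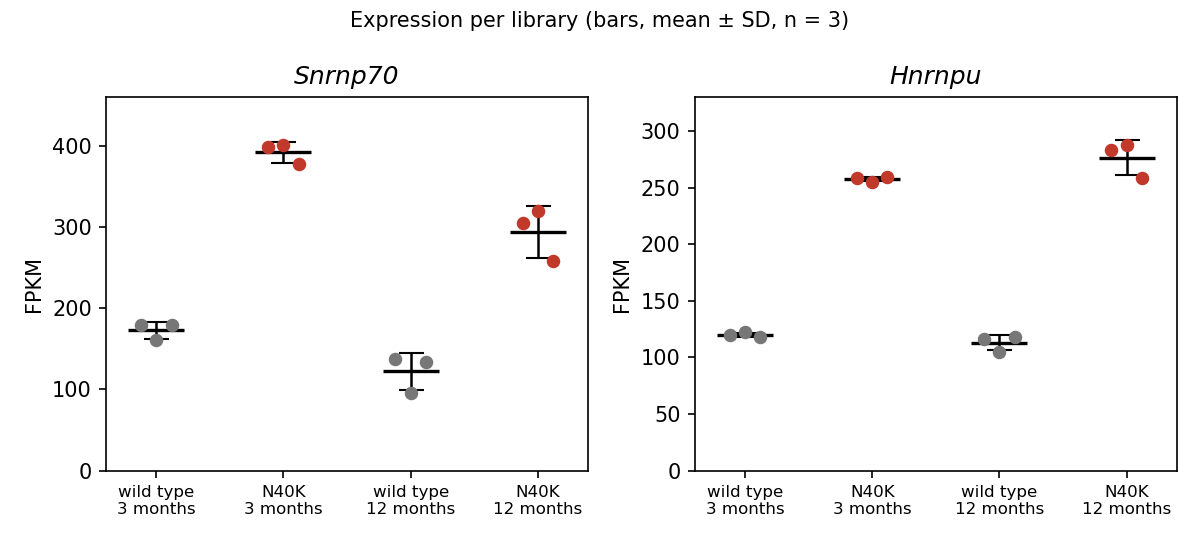
FPKM of Snrnp70 and Hnrnpu (vertical axes) in each library by genotype and age (horizontal axes), with the mean and SD of 3 mice. Every transgenic library lies above every wild-type library for both genes, at mean ratios of 2.27 and 2.41 for Snrnp70 and 2.15 and 2.44 for Hnrnpu at 3 and 12 months.

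The 3-month comparison asked what neuronal N40K changed in young adults. Among the genes with the largest rises were the galectin genes Lgals4, from 3.52 ± 0.85 to 11.1 ± 1.10 FPKM (SD, n = 3), and Lgals6, from 7.67 ± 1.97 to 23.9 ± 2.74 FPKM. These and the joined Lgals4;Lgals6 entry are near-identical copies, so the split of reads between them is uncertain. Dok3, a signalling adaptor gene, rose from 5.94 ± 0.82 to 18.4 ± 0.80 FPKM, and Sds, which encodes serine dehydratase, rose by 1.41 ± 0.14 (log2, SE), although its exons overlap those of Plbd2. On the log2(FPKM + 1) scale the largest fall was in Atp11b, a phospholipid flippase gene, from 21.5 ± 1.45 to 9.38 ± 0.28 FPKM. As a ratio of mean FPKM this was 0.436, and genes with lower levels, such as BC049635 at 0.154, fell further. Scg5, whose product is the chaperone of prohormone convertase PC2, fell from 115 ± 4.78 to 62.4 ± 3.51 FPKM.

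Further rises at 3 months, as log2 differences with SE, were 1.41 ± 0.18 for Gm14378, 1.23 ± 0.07 for Tcte2, 1.22 ± 0.11 for Dqx1, 1.18 ± 0.16 for Stac3 and 1.195 ± 0.15 for Ap1g2, an adaptor complex gene that overlaps Thtpa. Small RNA loci Snord55 (1.57 ± 0.40) and Mir5130 (1.41 ± 0.39, overlapping Kctd12) were also called, with adjusted p of 0.0265 and 0.0407. Further falls were -0.96 ± 0.07 for the tetraspanin gene Tspan18, -0.92 ± 0.09 for the uridine phosphorylase gene Upp2, -0.90 ± 0.06 for Gpcpd1, -0.87 ± 0.07 for B230217O12Rik (overlapping Fam160b1), -0.85 ± 0.09 for BC049635, -0.80 ± 0.13 for Spink10, -0.72 ± 0.14 for Epyc, -0.71 ± 0.10 for the cytidine deaminase gene Cda and -0.71 ± 0.12 for A330102I10Rik. Plxdc1 stood at -0.85 ± 0.22, with an adjusted p of 0.0298. Each of these genes separated the 3 transgenic from the 3 wild-type libraries without overlap, as the rule for naming them required. Of 13945 genes tested with limma, 1596 were called at an adjusted p under 0.05, 1109 higher and 487 lower. On the log2(FPKM + 1) scale the calls had a median size of 0.284, with 30 changes of at least 2-fold. The groups did not overlap for 31.9% of genes, against 10% by chance. The share of calls that were higher, 69.5%, was 53.5% with median-ratio scaling, 54.4% with quantile normalization, 54.0% with the transcript length trend removed and 52.9% with the GC trend removed, the last 2 chosen after seeing the data. With Xist as a covariate 1106 genes were called, 795 higher and 311 lower, and 67.4% of the 1596 were kept. The calls for Snord55, Mir5130 and Plxdc1 ended under several alternatives, among them the omission of replicate 2 of the transgenic group (adjusted p of 0.0964, 0.148 and 0.0907).

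Of the gene lists, replication-dependent histones rose most clearly at 3 months. Of 14 members, 11 rose, none fell and 3 were not called, and 12 rose when adjusted over the list alone. Their median log2 difference was 0.70, with a camera adjusted p of 5.46e-09, and an adjusted p of 0.938 with an estimated correlation. Hist1h4i rose from 2.54 ± 0.43 to 7.03 ± 1.30 FPKM (SD, n = 3), Hist1h1c from 7.85 ± 1.59 to 16.6 ± 5.25 FPKM and Hist1h2bg from 2.43 ± 0.46 to 5.11 ± 1.04 FPKM. These transcripts largely lack poly-A tails, so poly-A selected libraries measure only a part of them.

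Activity-regulated immediate early genes also stood higher at 3 months, with 3 of 29 called (3 adjusted over the list alone) and a median of 0.18 (adjusted p = 0.0274, and adjusted p = 0.938 with an estimated correlation). The called members were the transcription factor genes Egr4 (0.95 ± 0.19), Egr2 (0.76 ± 0.16) and Jun (0.34 ± 0.06). Over all genes 1109 of 13945 were called higher at this age, so 3 of 29 was near that share. The list lost its call without replicate 1 of the wild-type group (median 0.11, adjusted p = 0.201), replicate 2 (0.18, 0.143) or replicate 3 (0.14, 0.119) of the transgenic group, or replicate 2 of the 12-month wild-type group (0.18, 0.0542). It also lost it with the stricter filter of a mean of at least 5 FPKM (0.18, 0.0763).

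Oligodendrocyte genes had a median of -0.14 at 3 months (adjusted p = 0.00649, and adjusted p = 0.938 with an estimated correlation), with 0 of 24 members called by limma over all genes or adjusted over the list alone. The mean level of the list was 0.22, 0.34 and 0.29 above the average in the 3 libraries with Xist reads and 0.047, -0.050 and 0.080 in the other 3 libraries of that age. With Xist as a covariate its median was -0.069 and its adjusted p 0.0639, and without replicate 3 of the wild-type group they were -0.056 and 0.115. Without replicate 1 of the transgenic group they were -0.085 and 0.338, and without replicate 3 of the transgenic group -0.24 and 3.7e-08. Interferon response genes had a median of -0.24 at 3 months (adjusted p = 0.00929, and adjusted p = 0.938 with an estimated correlation), yet the only member called of 20, also when adjusted over the list alone, was Irf9 (overlapping Rnf31), higher by 0.37 ± 0.08. Replicate 3 of the wild-type group had the highest interferon level of that age, 0.28 above the average, and the highest level of Ttr, a marker of choroid plexus, at 5813 FPKM against 74.3 to 1699.9 FPKM in the other 3-month libraries. Without that library the median of the interferon list was -0.28 and its adjusted p 0.0514, and with the stricter filter they were -0.17 and 0.889.

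The 12-month comparison asked the same of older adults. The genes with the largest rises included Lgals6 (1.68 ± 0.15, log2 and SE), Lgals4 (1.48 ± 0.12), Gm14378 (1.40 ± 0.18), Tmem86b (1.35 ± 0.15), Dqx1 (1.33 ± 0.11) and Sds (1.31 ± 0.14). On the log2(FPKM + 1) scale Tspan18 showed the largest fall, from 7.34 ± 0.21 to 2.15 ± 0.14 FPKM (SD, n = 3). As a ratio of mean FPKM this was 0.293, and BC049635, with lower levels, fell further (0.153). Scg5 fell from 110.2 ± 11.8 to 52.3 ± 1.94 FPKM, and Ddn, which encodes the postsynaptic protein dendrin, from 389 ± 10.8 to 206 ± 11.1 FPKM. Sdf2l1, a gene of the endoplasmic reticulum, fell from 11.2 ± 2.27 to 4.56 ± 0.36 FPKM, and Chordc1, a co-chaperone of HSP90, from 32.2 ± 3.12 to 14.4 ± 0.55 FPKM.

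Small RNA loci among the 12-month rises were Mir125a (1.46 ± 0.21), Snord53 (1.42 ± 0.26), Snord19 (1.42 ± 0.17) and Mir199a-1 (1.41 ± 0.22). Bglap3 rose by 1.52 ± 0.35, a call that ended without replicate 2 of the wild-type group (1.21, adjusted p = 0.0502). Further falls were -1.21 ± 0.08 for Smoc2, -1.21 ± 0.09 for BC049635, -1.13 ± 0.09 for Upp2, -1.01 ± 0.14 for Epyc, -0.94 ± 0.10 for the mitochondrial ribosomal gene Mrps6 (overlapping Slc5a3), -0.93 ± 0.13 for Spink10 and -0.91 ± 0.05 for the adenylate kinase gene Ak5 (overlapping AI115009 and Zzz3). Limma called 2632 genes, 1557 higher and 1075 lower. On the log2(FPKM + 1) scale these had a median size of 0.284, with 44 changes of at least 2-fold. The share of calls that were higher, 59.2%, was 51.6% under quantile normalization and 50.2% with the stricter filter. The groups did not overlap for 38.8% of genes, against 10% by chance. All 6 libraries of this age had Y-linked reads.

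Genes of the unfolded protein and heat shock response fell together at 12 months. Of 24 members, 16 fell, none rose and 8 were not called, with 16 falling also when adjusted over the list alone. The median was -0.37, with a camera adjusted p of 2.38e-09, and an adjusted p of 0.816 with an estimated correlation. Hspa5, the main chaperone of the endoplasmic reticulum, fell from 141 ± 18.2 to 78.0 ± 8.56 FPKM (SD, n = 3) and Manf, which overlaps Rbm15b, from 21.7 ± 3.54 to 12.6 ± 0.74 FPKM. Pdia4 (-0.66 ± 0.14, overlapping Mir704), Creld2 (-0.51 ± 0.09), Xbp1 (-0.44 ± 0.09), Calr (-0.43 ± 0.07) and the cytosolic heat shock gene Hspa8 (-0.37 ± 0.07) fell as well. The mean level of the list was 0.25, 0.33 and 0.085 above the average in the wild-type libraries and -0.23, -0.17 and -0.069 in the transgenic ones. At 3 months it was -0.142, -0.072 and 0.028 in wild type and -0.031, -0.016 and 0.033 in transgenic libraries. The 12-month wild-type group thus stood above all other groups. Ttr was at 1282, 1053 and 2152 FPKM in the 12-month wild-type libraries and at 25.2, 223 and 2977 FPKM in the 12-month transgenic ones.

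Interferon response genes rose at 12 months, 9 of 20 over all genes tested and 17 when adjusted over the list alone, with none lower. Their median was 0.45 (adjusted p = 9.12e-07, and adjusted p = 0.816 with an estimated correlation). Ifi27l2a rose by 1.23 ± 0.37, Ifit1 by 0.90 ± 0.24 and Oasl2 by 0.77 ± 0.13, and the regulators Irf7 by 0.85 ± 0.17 and Irf9 by 0.70 ± 0.08. The transgenic libraries spread widely, at -0.088, 0.17 and 0.55 from the average against -0.26, -0.44 and -0.24 in wild type, and the highest of them was also the one with Ttr at 2977 FPKM. Endothelial and mural cell genes had a median of 0.22, with 5 of 24 higher, 7 adjusted over the list alone, and none lower (adjusted p = 4.12e-04, and adjusted p = 0.816 with an estimated correlation). The transporter genes Slco1a4 (0.62 ± 0.08) and Abcb1a (0.35 ± 0.07) and the receptor genes Tie1 (0.33 ± 0.09) and Flt1 (0.32 ± 0.07) were among them.

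**Figure D2:**
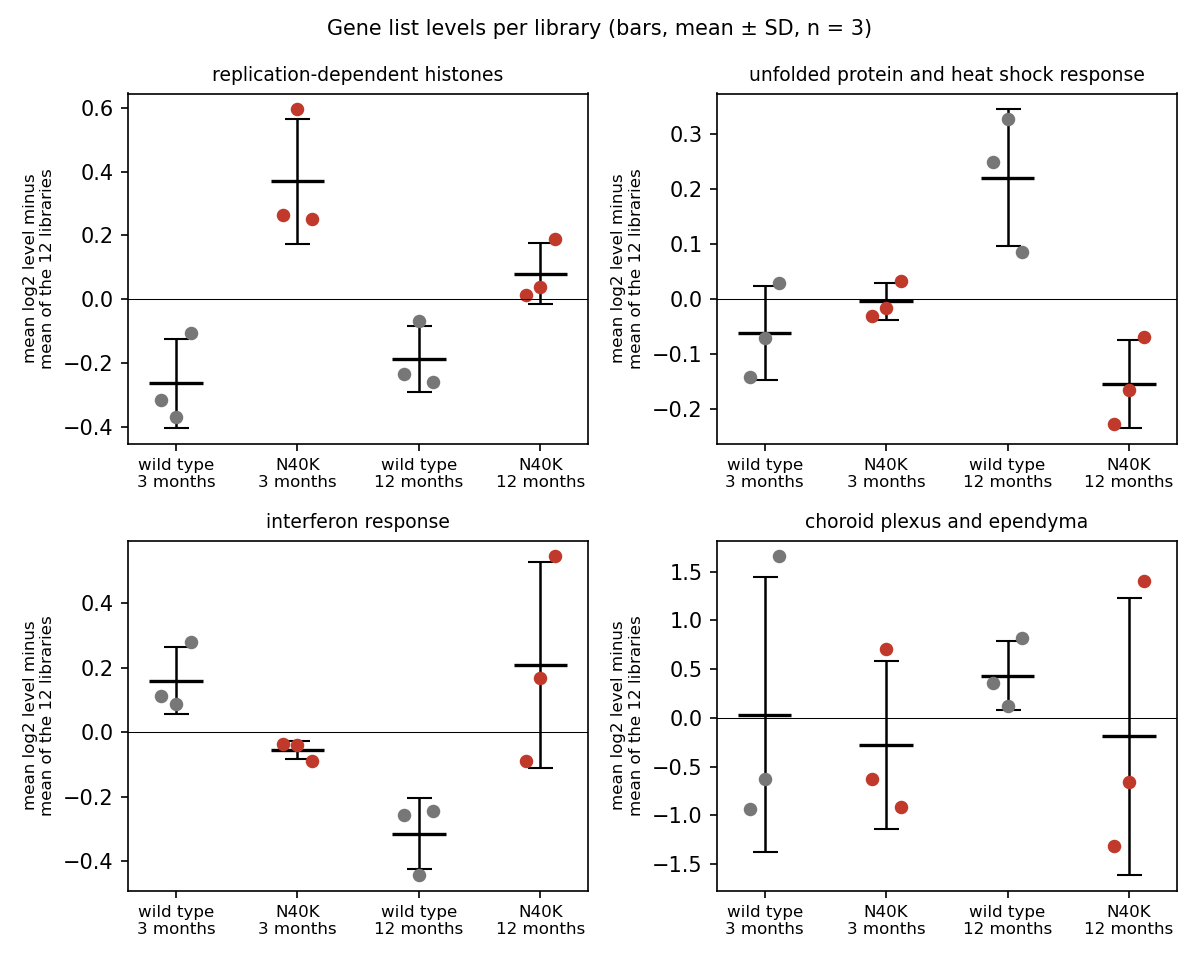
Mean log2 level of 4 gene lists in each library, relative to the mean of the 12 libraries (vertical axes), by genotype and age (horizontal axes), with the mean and SD of 3 mice. Histone genes lie higher in transgenic mice, and unfolded protein and heat shock genes separate the 12-month groups. Interferon genes vary most within the 12-month transgenic group, and choroid plexus genes vary widely within groups.

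Cytosolic ribosomal protein genes had a median of -0.13 at 12 months, with 11 of 58 lower, 12 adjusted over the list alone, and none higher (adjusted p = 2.05e-08, and adjusted p = 0.816 with an estimated correlation). Rpl3 fell by 0.31 on the log2 scale (SE 0.06) and Rps20 by 0.27 (SE 0.06). Oxidative phosphorylation genes had the same median, with 3 of 45 lower, 3 adjusted over the list alone, and none higher (adjusted p = 1.88e-06, and adjusted p = 0.816 with an estimated correlation). These members were Cox6c (-0.26 ± 0.06), Ndufa10 (-0.21 ± 0.05) and Uqcrc1 (-0.21 ± 0.05). Over all genes 1075 of 13945 were called lower at this age, so 3 of 45 was near that share. Quantile normalization ended both calls, with medians of -0.036 for ribosomal and -0.035 for oxidative phosphorylation genes and adjusted p of 0.0827 and 0.263. Without replicate 2 of the wild-type group, in which both lists stood above the average while they stood below it in the other 5 libraries of that age, the medians were -0.065 and -0.043, with adjusted p of 2.36e-04 and 0.00507.

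Immediate early genes stood lower at 12 months, with 3 of 29 called, 2 adjusted over the list alone, and a median of -0.14 (adjusted p = 0.013, and adjusted p = 0.816 with an estimated correlation). Fosb was at -0.44 ± 0.12, Jun at -0.27 ± 0.06 and Fosl2 at -0.27 ± 0.08. Over all genes 1075 of 13945 were called lower at this age, so 3 of 29 was near that share. The call ended without replicate 2 (median -0.10, adjusted p = 0.064) or 3 (-0.13, 0.0603) of the transgenic group or replicate 2 (-0.089, 0.0737) or 3 (-0.081, 0.0959) of the wild-type group, and with the stricter filter (-0.16, 0.0699). The median was -0.24 without replicate 1 of the wild-type group. Oligodendrocyte genes had a median of -0.14 with 0 of 24 called, also adjusted over the list alone (adjusted p = 0.00651, and adjusted p = 0.816 with an estimated correlation), a call that quantile normalization ended (-0.099, adjusted p = 0.0688). Histone genes had a median of 0.26, with 4 of 14 higher and 1 lower, 6 and 1 adjusted over the list alone (adjusted p = 0.0401, and adjusted p = 0.816 with an estimated correlation). Hist1h4i rose by 0.92 ± 0.13, and Hist2h2be was at -0.20 ± 0.06. That list lost its call under quantile normalization (0.26, adjusted p = 0.0525), with the stricter filter (0.23, 0.133) and without replicate 1 (0.23, 0.0673) or 3 (0.23, 0.0524) of the 3-month transgenic group, replicate 3 of the 12-month transgenic group (0.22, 0.0995), or replicate 1 (0.23, 0.107) or 3 (0.20, 0.187) of the 12-month wild-type group.

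Averaged over both ages, with 6 mice per genotype, the falls were led by Tspan18 (-1.18 ± 0.05, log2 and SE), BC049635 (-1.03 ± 0.06), Upp2 (-1.02 ± 0.07), Atp11b (-0.96 ± 0.05) and Scg5 (-0.96 ± 0.05), and the rises by Lgals6 (1.61 ± 0.11), Lgals4 (1.46 ± 0.09), Gm14378 (1.41 ± 0.13), Sds (1.36 ± 0.10), Dok3 (1.30 ± 0.09) and Dqx1 (1.27 ± 0.08). The small RNA locus AF357355 stood at -0.80 ± 0.19. Limma called 3493 genes, 2162 higher and 1331 lower, with a median size of 0.205, and both ages separated without overlap for 17.3% of genes, against 1% by chance. With Xist as a covariate 3100 genes were called, and 86.8% of the 3493 were kept. The share of calls that were higher, 61.9%, was 49.8% under quantile normalization, 51.7% with the length trend removed and 51.1% with the GC trend removed. Across genes, which are not independent replicates, the genotype effects at the 2 ages correlated at r = 0.539 (Spearman rho 0.453). Of 100 splits of the genotype labels within ages, 6 gave a correlation at least as far from 0 (permutation p = 0.06). These include the real split and the split with the labels of 1 age exchanged, which must give the same size with the opposite sign. Of 3300 genes called at either age, 2799 (84.8%) had the same sign at both. At both ages 602 genes were called higher, where independent lists would share 124, and 313 lower, where they would share 37.5, while 13 were called in opposite directions. The expected numbers are no fair baseline, since both contrasts used 1 estimate of the spread per gene and genes are not independent.

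**Figure D3:**
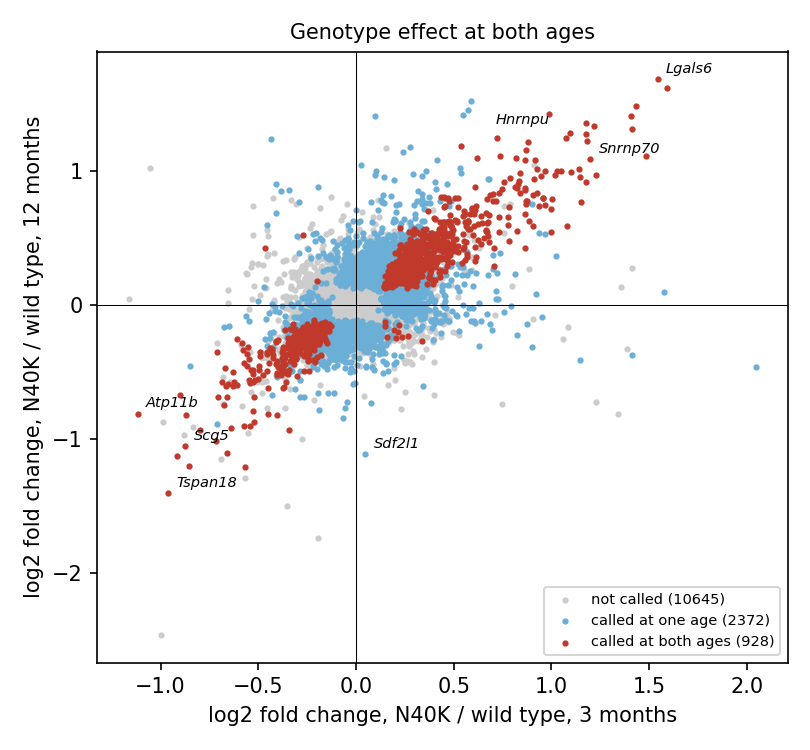
Log2 fold change of each tested gene, transgenic over wild type, at 3 months (horizontal axis) and 12 months (vertical axis). The 928 genes called at both ages are red, the 2372 called at one age blue, and the others grey, and most of the red points lie in the quadrants of the same sign.

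Splicing factor genes moved in both directions over both ages. Over all genes 3493 of 13945 were called in this contrast, 2162 higher and 1331 lower, so member counts near that share are no trait of a list. In the U1 snRNP list 5 of 15 rose and 1 fell, also when adjusted over the list alone, but Snrnp70 among the rises may hold reads of the transgene. Besides Snrnp70 the rises were in Luc7l2 (0.36 ± 0.06), Luc7l (0.25 ± 0.05), Snrpa (0.11 ± 0.03, overlapping BC024978) and Taf15 (0.17 ± 0.05), and Tial1 fell by 0.17 on the log2 scale. The list was not called (median 0.032, camera adjusted p = 0.575). In the Sm core and U2 snRNP list Sf3b3, which overlaps Cog4, rose by 0.50 ± 0.03 and Sf3b1 by 0.18 ± 0.03, while the joined entry Snrpn;Snurf fell by 0.42, with 3 of 25 higher and 4 lower by both adjustments, the second over the list alone (adjusted p = 0.779). Of 31 tri-snRNP and catalytic spliceosome genes 3 rose and 4 fell, 5 and 4 adjusted over the list alone (adjusted p = 0.575), among them Snrnp48 (0.22 ± 0.04) and Snrnp35 (-0.23 ± 0.04). Of 49 SR, hnRNP and neuronal splicing regulators 7 rose and 10 fell, 9 and 11 adjusted over the list alone (adjusted p = 0.634). Next to Hnrnpu, Nova2 (0.23 ± 0.03), Srsf6 (0.22 ± 0.04) and Srsf1 (0.19 ± 0.03) rose, and Hnrnph1 (-0.25 ± 0.04), Celf4 (-0.21 ± 0.04), Tra2a (-0.19 ± 0.03) and Srsf7 (-0.19 ± 0.03) fell.

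Single synaptic genes were called over both ages, while their lists were not. Here too 3493 of all 13945 genes were called, so member counts near that share are no trait of a list. Of 19 GABA receptor and inhibitory postsynapse genes, 1 rose and 5 fell, 2 and 6 adjusted over the list alone (adjusted p = 0.381), with the receptor subunit genes Gabra3 (-0.62 ± 0.12) and Gabra2 (-0.46 ± 0.06) and the scaffold gene Gphn (-0.23 ± 0.03) lower and Nlgn2 (0.20 ± 0.04) higher. Of 34 glutamate receptor and excitatory postsynapse genes 3 rose and 4 fell by both adjustments, the second over the list alone (adjusted p = 0.733), including Cacng8 (-0.28 ± 0.04) and Camk2a (-0.18 ± 0.04). Of 30 presynaptic vesicle release genes 4 rose and 4 fell, 4 and 5 adjusted over the list alone (adjusted p = 0.198), with Vamp1 (-0.50 ± 0.06) and the glutamate transporter gene Slc17a7 (-0.23 ± 0.04) lower and Nrxn2 (0.19 ± 0.03) higher. In the interneuron list the neuropeptide genes Cort (0.45 ± 0.06) and Tac1 (0.56 ± 0.14) rose, with 3 of 27 higher and 1 lower by both adjustments, the second over the list alone (adjusted p = 0.925). Pyramidal neuron genes split 2 higher and 4 lower of 20 (adjusted p = 0.719), with Wfs1 at 0.45 ± 0.09 and Spink8 at -0.52 ± 0.09, and dentate granule genes 3 higher and 1 lower of 20 (adjusted p = 0.779), with Tdo2 at 0.48 ± 0.09 and Plk5 at -0.55 ± 0.12, the counts of both lists being equal when adjusted over the list alone.

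Among the lists already described, those called over both ages were histones (11 of 14 higher, 11 adjusted over the list alone, median 0.44, adjusted p = 4.32e-05), unfolded protein and heat shock genes (9 of 24 lower, 12 adjusted over the list alone, median -0.14, adjusted p = 2.23e-04), oligodendrocytes (3 of 24 lower, 3 adjusted over the list alone, median -0.13, adjusted p = 9.19e-04), ribosomal proteins (4 of 58 lower, 1 adjusted over the list alone, median -0.039, adjusted p = 0.0124) and oxidative phosphorylation (5 of 45 lower, 3 adjusted over the list alone, median -0.039, adjusted p = 0.0153). Each had an adjusted p of 0.992 with an estimated correlation. Over all genes 1331 of 13945 were called lower, so the counts of oligodendrocyte, ribosomal and oxidative phosphorylation genes were near that share. At 3 months alone 3 of the 5 lists had medians above 0 and were not called by camera. They were unfolded protein and heat shock genes (0.073, 15 of 24 members above 0, adjusted p = 0.76), ribosomal proteins (0.049, 50 of 58, 0.425) and oxidative phosphorylation (0.028, 31 of 45, 0.76). Their averaged falls thus came from 12 months. The myelin genes Mobp (-0.27 ± 0.06), Mal (-0.23 ± 0.06) and Tspan2 (-0.17 ± 0.05) were the oligodendrocyte members called. Without replicate 2 of the 12-month wild-type group the ribosomal and oxidative phosphorylation medians were -0.008 and -0.007, with adjusted p of 0.459 and 0.396. Those 2 lists also lost their calls under quantile normalization (adjusted p of 0.993 for both), with the stricter filter (0.0871 for both), without replicate 1 of the 3-month wild-type group (0.118 and 0.0837) and without replicate 1 of the 3-month transgenic group (0.199 for both), and the ribosomal median was -0.061 without replicate 3 of the 12-month wild-type group.

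Few genes were called over both ages among the remaining markers of glia and of other cell types. None of 20 astrocyte genes was called (adjusted p = 0.845). Of 26 microglia genes Cd68 (0.15 ± 0.04) was called, and of 18 genes of disease-associated microglia Lyz2 (0.24 ± 0.08), neither when adjusted over the list alone (adjusted p of the lists 0.629 and 0.776). Of 19 reactive astrocyte genes C4b (0.18 ± 0.06) rose and Serpina3n (-0.20 ± 0.06) fell, and neither was called when adjusted over the list alone (list adjusted p = 0.575). C4b was also the member called of 20 antigen presentation and complement genes, 0 adjusted over the list alone (list adjusted p = 0.779). Of 14 oligodendrocyte precursor genes Olig2 fell by 0.30 on the log2 scale (1 adjusted over the list alone, list adjusted p = 0.279), and at 12 months Olig2 (-0.59 ± 0.09), Olig1 (-0.34 ± 0.08) and C1ql1 (-0.26 ± 0.07) fell. Of 15 p53 and cell death genes Casp1 (0.48 ± 0.13), Bbc3 (0.21 ± 0.07) and Aen (0.11 ± 0.04) rose, 1 adjusted over the list alone (list adjusted p = 0.992). Of 22 genes of amyloid precursor and tau processing Cdk5 (-0.13 ± 0.03) and App (-0.12 ± 0.04) fell and Cdk5r1 (0.11 ± 0.03) rose, by both adjustments, the second over the list alone (list adjusted p = 0.779). No gene was called among 21 choroid plexus and ependyma genes (median -0.42, adjusted p = 0.198), 21 genes of neighbouring brain regions (adjusted p = 0.998), 6 blood genes (adjusted p = 0.634) or the 5 genes of the sex chromosomes (adjusted p = 0.873).

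The interaction asked whether the genotype effect differed between the ages. Gbp3, a guanylate-binding protein gene induced by interferon, stood at 3.82 ± 0.13 and 2.50 ± 0.33 FPKM in wild-type and transgenic mice at 3 months and at 1.51 ± 0.19 and 2.37 ± 0.26 FPKM at 12 months (SD, n = 3), a change of the genotype effect by 0.89 ± 0.12 (log2, SE). The class I histocompatibility entries LOC547349 (0.79 ± 0.10) and H2-D1;H2-L (0.68 ± 0.10), which share sequence with related genes and are uncertain, Mir23b (0.68 ± 0.08) and the transferrin receptor gene Tfrc (0.54 ± 0.07) moved the same way. Jun (-0.61 ± 0.09), 9530052E02Rik (-0.84 ± 0.10, overlapping Irs2), Ramp2 (-0.50 ± 0.07) and Klhl26 (-0.40 ± 0.06) moved the other way. These 9 genes were the limma calls, with adjusted p from 0.0246 to 0.0407, beside 1997 genes at an unadjusted p under 0.05. With Xist as a covariate 0 were called (1832 at an unadjusted p under 0.05), and leaving out single libraries gave 0 to 162 calls. Camera called 13 of the 30 lists, among them interferon response (median 0.65, adjusted p = 1.15e-15) and unfolded protein and heat shock response (-0.43, adjusted p = 7.53e-13), each with 0 of its members called over all genes and 15 higher and 17 lower adjusted over the list alone. Both had an adjusted p of 0.537 with an estimated correlation.

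Between 12 and 3 months, averaged over both genotypes, the largest rises were in the NMDA receptor subunit genes Grin2b (2.62 ± 0.08, log2 and SE) and Grin2a (2.45 ± 0.06), the cytoskeletal linker gene Dst (2.48 ± 0.05), Zbed6 (2.31 ± 0.12) and Lnpep (2.29 ± 0.10). The largest falls were in Rpph1 (-3.88 ± 0.23) and Rmrp (-2.85 ± 0.24), RNA components of ribonucleases that carry no poly-A tail, Acta2 (-1.52 ± 0.27) and Tnfrsf25 (-1.45 ± 0.15). Xist (-2.002 ± 0.78) was also called, and it stood at 13.5 to 17.3 FPKM in 3 libraries, all from 3-month mice, and at most at 0.112 FPKM in every other library. Limma called 8452 genes, 2463 higher and 5989 lower, and the share of higher calls, 29.1%, was 48.5% with median-ratio scaling, 45.8% under quantile normalization, 49.3% with the length trend removed and 48.5% with the GC trend removed. With Xist as a covariate 6992 genes were called, 6876 of them among the 8452. Every library name of 1 age belonged to 1 of 2 number series, so library batch and age could not be told apart. Sex, by the Xist reads, was unbalanced between the ages as well. Ribosomal protein genes (1 higher and 46 lower of 58, equal adjusted over the list alone, adjusted p = 8.36e-06) and oxidative phosphorylation genes (32 of 45 lower, 32 adjusted over the list alone, adjusted p = 0.00106) had lower levels, as did the Sm core and U2 snRNP (19 of 25 lower, 1 higher and 20 lower adjusted over the list alone, adjusted p = 0.00883) and oligodendrocyte (17 of 24 lower, 18 adjusted over the list alone, adjusted p = 0.0257) lists. Glutamate receptor (19 of 34 higher, 6 lower, adjusted p = 8.97e-05), GABA receptor (9 of 19 higher, 3 lower, adjusted p = 0.0016), presynaptic (14 of 30 higher, 7 lower, adjusted p = 0.00106) and interneuron (12 of 27 higher, adjusted p = 8.36e-06) lists had higher levels, with equal counts adjusted over the list alone. With an estimated correlation these 8 adjusted p ran from 0.584 to 0.946, and with the length trend removed the calls for Sm core and U2 snRNP (0.158), GABA receptors (0.0616), glutamate receptors (0.49), presynaptic genes (0.125) and oxidative phosphorylation (0.815) ended. The oxidative phosphorylation call also ended under quantile normalization (median -0.05, adjusted p = 0.144). The oligodendrocyte call, at a median of -0.31, ended with Xist as a covariate (-0.16, adjusted p = 0.336), with the stricter filter (-0.33, 0.0632) and without replicate 2 of the 12-month wild-type group (-0.33, 0.0565).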

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

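The tests of library batch, of a denser gene neighbourhood, of the stratified neighbour shares, of neighbour shares by the mean of all libraries, of interaction splits with the genotype effect removed and of the scaling of the deposited values were chosen only after the results were seen, as were the corrections for Ttr and transcript length.

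The genotype effect differed between 12 and 3 months, by the interaction test, for 9 genes. The effect at 12 months was above that at 3 months by 0.89 for Gbp3, 0.79 for LOC547349, 0.68 for H2-D1;H2-L, 0.68 for Mir23b and 0.54 for Tfrc (log2). It was below it, with differences of -0.84 for 9530052E02Rik, -0.61 for Jun, -0.50 for Ramp2 and -0.40 for Klhl26. In 4 of 100 splits of the libraries at least 9 genes were called, but these splits are no fair comparison, since the large averaged genotype effect enters the spread of the others and, when the labels of 1 age are exchanged, becomes the interaction itself (3493 genes, with 64 in the highest of the remaining splits). With the averaged effect removed from the values, 1 of 100 splits, the real one, called at least 9 genes and the highest other called 6. That effect was estimated with the real labels, so its removal left the real interaction as it was and took spread from the other splits, which favoured the real split in advance. Neither set of splits is thus a fair test, and whether chance can be excluded stays open. The calls also rest on few libraries, as limma called 0 with the replicate block (1506 at an unadjusted p under 0.05), with Xist as a covariate (1832) and in 6 of 12 leave-one-out fits (1565 to 1928).

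By the same test 13 gene lists differed between the ages, each with an adjusted p from 0.537 to 0.558 with an estimated correlation. Transcript length correlated with the interaction effect at rho = 0.313. As library series coincided with age, a difference between the ages could not be told from a difference between batches. Sex was also unbalanced, as the only libraries with Xist reads were from 3-month mice. The median difference was 0.65 for interferon response, 0.25 for antigen presentation and complement, 0.24 for endothelial and mural cells, 0.20 for reactive astrocytes, 0.14 for U1 snRNP and 0.07 for glutamate receptors. It was -0.43 for unfolded protein and heat shock response, -0.39 for replication-dependent histones, -0.30 for immediate early genes, -0.17 for dentate granule neurons, -0.66 for blood, -0.18 for ribosomal proteins and -0.16 for oxidative phosphorylation. The call of blood ended under many alternatives, among them Xist as a covariate (adjusted p = 0.057), the replicate block (0.063), the length trend removed (0.251) and the GC trend removed (0.119). Only 66.7% of the 6 tested blood genes had a length, so both trend removals left members out, which could itself have ended the call. That of glutamate receptors ended with no filter (0.0692), the length trend removed (0.903), Ttr as a covariate (0.0978) and without any of 7 single libraries (0.0607 to 0.143). Reactive astrocytes lost the call with the stricter filter (0.352) and without any of 3 libraries (0.0575 to 0.152), dentate granule neurons without replicate 2 of the 3-month transgenic (0.0693) or replicate 1 of the 12-month wild-type group (0.0539), and U1 snRNP with the GC trend removed (0.0527). Single libraries moved several of these medians by over 1.5 times. Without replicate 3 of the 3-month wild-type group the antigen presentation median was 0.06 and that of reactive astrocytes 0.05, and without replicate 3 of the 3-month transgenic group they were 0.153 and 0.071. Without replicate 3 of the 12-month transgenic group they were 0.138 and 0.111, and without replicate 1 of that group antigen presentation was 0.384 and U1 snRNP 0.076. Without replicate 2 of the 12-month wild-type group the medians were 0.05 for U1 snRNP, 0.044 for glutamate receptors, -0.288 for dentate granule neurons, -0.08 for oxidative phosphorylation and -0.105 for ribosomal proteins. Without replicate 2 of the 3-month transgenic group they were 0.029 for glutamate receptors, -0.108 for dentate granule neurons, -0.404 for blood and -0.232 for histones, without replicate 3 of that group -0.283 for dentate granule neurons, and without replicate 2 of the 3-month wild-type group -0.423 for blood.

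Unfolded protein, ribosomal protein and oxidative phosphorylation genes stood lower in transgenic mice at 12 months. Removing the transcript length trend left medians of -0.355, -0.079 and -0.075 (adjusted p of 1.97e-08, 3.21e-05 and 3.76e-04), and Ttr as a covariate left -0.316, -0.125 and -0.116 (adjusted p of 1.65e-09, 5.82e-09 and 2.96e-06), which argues against length and choroid plexus as the whole cause. Quantile normalization left -0.287 for unfolded protein genes (adjusted p = 4.17e-08, SD of members 0.276 before and 0.290 after). It took the other 2 lists from -0.128 to -0.036 (adjusted p = 0.0827, SD 0.079 before and 0.087 after) and -0.035 (adjusted p = 0.263, SD 0.0623 and 0.0645). These 2 calls ended because the medians shrank while the spread did not. Median-ratio scaling, with a single factor per library, ended neither call. Quantile normalization gives every library the same distribution, which can also take out a real shift of a list. Whether the distributions of the deposited values account for these 2 calls thus stays open. The effect of N40K at this age stays open as a hypothesis for the unfolded protein genes, as do causes that were not tested.

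Among genes with low levels most calls over both ages were higher in transgenic mice: by the mean of the 12 libraries 79.3% of calls under 5 FPKM, 66.3% from 5 to 20 FPKM and 37.7% above 20 FPKM. Placed by the wild-type mean, which enters the difference itself, the shares were 82.7%, 65.8% and 33.9%, so a part of that steeper gradient came from the placement. Of 851 genes under 5 FPKM in wild type called higher, 25.9% had an expressed gene of the same strand ending within 10 kb upstream, against 16.0% of 3537 not called (odds ratio 1.83, Fisher exact p = 1.08e-10) and 14.8% of 176 called lower, and the odds ratio was 1.67 (p = 4.59e-08) when stratified by downstream neighbour and expression. With genes placed by the mean of the 12 libraries the shares were 25.7% and 16.0% (odds ratio 1.81, Fisher exact p = 1.38e-09, 1.74 when stratified). The Fisher exact and stratified tests in this paragraph take genes as independent, so their p-values hold no spread between mice. Read-through from upstream genes may thus contribute for a part of them. Of the 220 upstream genes 48 were themselves called higher and 23 lower, beside 2162 and 1331 of all 13945 genes, so most were not called higher. Overlap with exons of other genes was found for 16.2% against 14.6% (Fisher exact p = 0.239), so most of these genes had no such overlap, which argues against overlapping reads as the whole cause. A downstream neighbour was found for 21.4% against 15.9% (odds ratio 1.44, Fisher exact p = 1.62e-04), with an interval of 1.19 to 1.75 that overlaps the upstream one of 1.52 to 2.19, so a denser neighbourhood stays open, as does scaling.

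The age comparison called 8452 genes, and 6767 with the transcript length trend removed. Of the 8392 original calls with a length 4912 (58.5%) were among these, so that trend was not the whole cause, while the other calls ended without it. Transcript length correlated with the age effect at rho = 0.459. Of the number series of the library names 0 held both ages, so library batch and age cannot be told apart. Sex was also unbalanced, as the only libraries with Xist reads were from 3-month mice. With Xist as a covariate limma called 6992 genes. The fall of Rpph1 and Rmrp, which carry no poly-A tail, is a measure that library preparation could change. In 1 of 100 splits, the real one, at least 8452 genes were called, with 3814 in the highest other split. That is the smallest share that 100 splits can give, which argues against chance but says nothing of batch or sex.

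The averaged genotype comparison called 3493 genes in the real split and 9 in the highest other. Only the real split, 1 of 100, called as many, the smallest share that 100 splits can give, which argues against chance. At 3 months the real split called 1596 and the highest other 8, and at 12 months 2632 and 0, each 1 of 10 splits, which are too few for a share under 0.05.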

How the results depend on the processing

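Ttr as a covariate and the removal of the length and GC trends were chosen only after the data were seen. Of 9094 alternative values of named genes 7802 kept direction and side of the threshold, 1292 weakened and 0 reversed, and of 3600 values of gene lists 3383 kept both, 110 weakened, 104 strengthened and 3 reversed. The named gene results were all selected as called in the main fit, so none could strengthen. From 4 to 13 of the 30 lists were called per contrast, so most list values that kept both were of lists that stayed uncalled. These totals thus do not measure how stable the calls were. The reversals were ribosomal proteins averaged over both ages, whose test changed sign under quantile normalization (median -0.003, adjusted p = 0.993), and choroid plexus genes with Ttr as a covariate, at 12 months (0.420, adjusted p = 0.0221) and in the interaction (0.373, adjusted p = 0.00858), where Ttr is itself a member of the list. With the replicate block 637 genes were called at 3 months, 1399 at 12 months and 0 in the interaction by limma (1506 at an unadjusted p under 0.05), although replicate numbers did not pair the mice. Each age fitted alone, with fewer libraries behind the spread, gave 1532 calls at 12 months. Leave-one-out fits gave 796 to 2227 calls at 3 months, with 1013 and 796 without wild type replicates 1 and 2 and 863 and 870 without transgenic replicates 2 and 3 of that age. They gave 1337 to 2607 at 12 months, with 1337 and 1384 without transgenic replicates 1 and 2 of that age. Averaged over both ages they gave 2699 to 3477 and for age 7874 to 8695. In the interaction they gave 0 to 162 calls, with 162 without replicate 1 of the 3-month transgenic group, 20 without replicate 3 of the 12-month wild-type group, 1 without replicate 3 of the 3-month wild-type group and 3 without replicate 2 of the 3-month transgenic group. Limma called 0 without replicates 1 or 2 of the 3-month wild-type group (1891 and 1666 at an unadjusted p under 0.05), replicate 3 of the 3-month transgenic group (1565), replicates 2 or 3 of the 12-month transgenic group (1582 and 1928) and replicate 2 of the 12-month wild-type group (1656). The interaction also had 0 calls with Xist as a covariate (1832 at an unadjusted p under 0.05) and 4 with the GC trend removed. Where fewer libraries were not the reason, the cause was not tested. Depths of 39.96 to 97.08 M reads limit the precision of genes with low FPKM.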

Other observations

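The tests in this part, on small RNA loci, their host genes and genomic span, with their jackknife, matching by level and length correction, were chosen only after the results were seen.

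Small nucleolar RNA and microRNA loci such as Snord53, Snord19 and Mir125a were among the largest rises at 12 months, which led to the hypothesis that unspliced introns of their host genes are retained in transgenic mice. The hosts of these 3 loci, Wdr43 (0.369), Gnl3 (0.493) and Ncrna00085 (0.531, all log2), were themselves called higher over both ages by limma. Of 300 such loci tested, 16.3% were called higher over both ages (49, with 11 lower), against 15.5% of 13645 other genes (odds ratio 1.07, Fisher exact p = 0.687), so the class as a whole was not shown to be called higher more often and the hypothesis stays open. Over the 228 loci with a tested host, the locus effect exceeded that of its host by a median of 0.067 (bootstrap SE 0.016), with 147 above 0. The bootstrap over loci holds no spread between mice, and a jackknife over libraries gave an SE of 0.022. Loci had lower levels than hosts (median 7.31 against 19.7 FPKM), and with each set against 100 genes of similar level the median was 0.045 (bootstrap SE 0.013, jackknife SE 0.025), which is less than 2 SE from 0, so host levels stay open as a cause. For the 34 called higher with a tested host the median was 0.389, with 33 above 0, but these were selected for being higher. For 15 of them the host was itself called higher, beside 2162 of all 13945 genes. These short transcripts are poorly captured by poly-A selection, and introns were not analysed here.

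U1 snRNP also protects transcripts from premature ends within introns, so long genes might fall if N40K disturbed this role. The rank correlation of genomic span with the genotype effect over 13011 protein-coding genes was -0.261 at 3 months and 0.086 at 12 months, with jackknife SE over libraries of 0.064 and 0.065. At 12 months it was 0.025 without replicate 2 of the wild-type group. With the transcript length trend removed it was -0.182 (jackknife SE 0.024) at 3 months and -0.047 (jackknife SE 0.013) at 12 months, so its sign at 12 months depended on that correction and the hypothesis stays open. Transcript length, which goes with the libraries as well as with genotype, correlated with the genotype effect at -0.127 at 3 months and 0.178 at 12 months.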
